A study of Mus musculus with 18 samples.

How the data were processed

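RNA of adrenal glands from C57BL/6N mice 2 months old was measured on Illumina bead arrays. The 18 arrays fall into 6 groups of 3: intact males, females and castrated males, each wild type or with the Ephb6 gene knocked out. Per the labels' protocols, RNA was purified on RNeasy columns, checked on a Bioanalyser and amplified to biotinylated cRNA with an Illumina kit. The labels number the samples of a group and do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

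The deposited table of bead signals gives, per the file headers, an average signal in intensity units and a detection p-value for each of 45281 probes on each array. These signals were not normalized between arrays, and the submitters' processing notes name GenomeStudio, with a version not given in the sources used here. A further deposited table holds the authors' normalized intensity values. Each of its columns has the same order of probes as the bead signals of its array. All 18 columns have nearly the same median (142.357 to 142.403) and their lowest value is 113.277. The table is thus on a linear scale after a quantile-like normalization whose exact method is not given in the sources used here. No slide or scan is named in the sources used here, so no slide effect could be fitted. No 2 arrays held identical values, and the highest correlation between any 2 arrays was 0.991.

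Background was corrected and signals were quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with the negative controls inferred from the detection p-values and an offset of 16 before log2. Probes with a detection p under 0.01 on at least 3 arrays were kept. The platform annotation gives 1 gene symbol for 34885 probes, several for 18 and none for 10378. Of the probes with 1 symbol, 34807 had a gene identifier in the RefSeq gene table, which changed 0 symbols. After the filter 18158 probes were left, of which 15717 had 1 symbol. For each of the 10375 genes the probe with the highest mean was tested, and 3775 genes had more than 1 probe left. The 2441 probes left without a single symbol were tested apart from the genes.

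The knockout effect was the difference between knockout and wild type in intact males, in females and in castrated males, and the mean of these 3. The sex and castration effects were the differences of females and of castrated males from intact males, within each genotype. The last set was the differences between the knockout effects of the 3 conditions. All were contrasts of a single limma fit of all 18 arrays with 12 residual degrees of freedom, an intensity trend in eBayes (prior degrees of freedom 6.20) and Benjamini-Hochberg adjustment. A gene passed at an adjusted p under 0.05. All fold changes are on the log2 scale, with the standard error of the fit. With 3 arrays per group, the number of arrays limits the precision: the median standard error was 0.206 for a difference of 2 groups, 0.119 for the mean knockout effect and 0.291 for a difference of knockout effects. Where the dimmer group's arrays never detected a gene, the fold is given as at least N-fold: the mean of the brighter group over the mean, per dim array, of the higher of the gene's own value and the lowest value of any detected probe.

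Gene lists were tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the data, and with fry. The lists were catecholamine synthesis and storage, chromaffin cell identity, nicotinic and calcium-driven exocytosis, steroidogenesis, cholesterol synthesis and SREBP2 targets, zona glomerulosa, X-zone, sex-chromosome genes, steroid receptors and sex-steroid metabolism, Eph receptors and ephrins, and the neighbours of Ephb6 on chromosome 6. Further lists were immediate early genes, glucocorticoid-induced genes, circadian clock, heat shock and unfolded protein response, interferon response, proliferation, mitochondrial complex I, and glutathione and xenobiotic metabolism. Markers of other cells and tissues were macrophages and antigen presentation, lymphocytes, endothelium, fibroblasts and capsule, Schwann and sustentacular cells, smooth muscle, adipose tissue, kidney, pancreas, liver, skeletal muscle and red blood cells. The X-zone and pancreas lists had 2 genes tested each and were not put to the set tests, which left 29 lists. The genes named were the 12 largest increases and 12 largest decreases among genes that passed and whose 2 groups' arrays did not overlap. Where fewer than 10 genes passed, the smallest p-values were added up to 10 genes. Up to 4 members of each list described, Ephb6, and Th, Ddc, Dbh, Pnmt, Star, Cyp11a1, Cyp11b1, Cyp11b2 and Akr1c18 were also named, and a further gene of the rule is not reported here. The groups, contrasts, lists, naming rule, limma and set tests were chosen before the data were examined. So were the alternatives, except for the fits and counts stated below as chosen after the data were seen. The tests of explanations were chosen after.

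The alternatives were no background correction, median scaling, cyclic loess, the authors' normalized values, other filters on dim probes, other treatments of several probes per gene, no intensity trend, array weights, the replicate number as a block, a fit of only the arrays of the groups compared, and each array left out in turn. The fit without castrated knockout array 1 was added after the data were seen. The limma fit was tested on simulated log2 values for the 10375 genes, with independent normal noise. At each of 4 fold sizes 50 genes were changed. Background correction, normalization, the filter and the choice of probes were not part of the simulation. It held no correlation between genes and no outlying array, so the numbers called may differ on the real arrays. For knockout against wild type in intact males, limma called 13 of 50 genes changed 1.5-fold, 34 of those changed 2-fold, 46 of those changed 3-fold and 50 of those changed 4-fold, and 10 of 10175 unchanged genes. For the mean knockout effect it called 35, 47, 50 and 50, and 6 unchanged genes. In the simulated female against intact male comparison in wild type, it called 16, 34, 48 and 50, and 13 unchanged genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.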

Results

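The arrays compared adrenal glands of intact male, female and castrated male mice with and without Ephb6, a receptor of the Eph family, which binds ephrins on neighbouring cells. The adrenal gland holds a steroid-producing cortex and a medulla of chromaffin cells, which make catecholamines. On 17 of the 18 arrays the mean bead signal lay between 446 and 640, and 34.6% to 37.9% of probes were detected. Each group had n = 3 arrays. Castrated knockout array 1 was dimmer, with a mean signal of 244 and 27.8% of probes detected. Its mean correlation with the other arrays of its group was 0.957, against 0.970 to 0.987 for the others. Knockout female array 1 also stood apart: it had the 0.970, and its Xist was the lowest of the female arrays. In the fit with array weights, the lowest weights were 0.16 for castrated knockout array 1 and 0.28 for knockout female array 1. The other arrays had weights of 0.45 to 2.74. Xist, which silences an X chromosome in female cells, averaged 9.70 in log2 intensity on the female arrays (8.14 to 10.2) and 4.49 on those of males and castrated males (4.29 to 4.69). Eif2s3y, a gene of the Y chromosome, averaged 4.46 on the female arrays and 8.02 on the others (7.01 to 8.97).

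Ephb6 RNA was lower in knockout than in wild-type adrenals. The mean difference over the 3 conditions was -1.14 (SE 0.15, limma adjusted p = 0.00481), taken partly against background, and it was -0.37 without background correction and -0.42 in the authors' normalized values. Ephb6 was the 1 gene of 10375 that passed in the mean knockout effect. In log2 intensity Ephb6 averaged 6.00 ± 0.33 (SD, n = 3) in wild-type intact males and 5.44 ± 0.50 in knockout ones, a difference of -0.55 (SE 0.26, adjusted p = 0.9997). In females it averaged 6.77 ± 0.32 in wild type and 5.30 ± 0.30 in knockout, a difference of -1.47 (adjusted p = 0.233). In castrated males it averaged 6.76 ± 0.07 and 5.35 ± 0.15, at least 1.82-fold lower with 0 of 3 knockout arrays detecting it (adjusted p = 0.386). The intact males overlapped: the knockout arrays lay at 4.89, 5.58 and 5.86 and the wild-type arrays at 5.73, 5.90 and 6.37. In all 3 conditions the probe is near background, and whether it lies inside the deleted part of the gene is not given in the sources used here, so its level is a limited check of the labels.

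**Figure D1:**
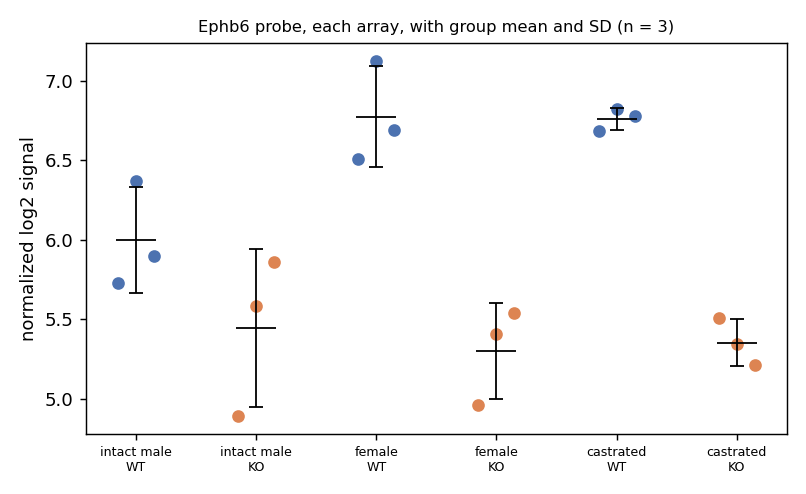
Ephb6 in log2 normalized intensity on each of the 18 arrays, by condition and genotype, with points for arrays, a line for the mean and bars for the SD (n = 3). The knockout means lie between 5.30 and 5.44, and the wild-type means are 6.00 in intact males, 6.77 in females and 6.76 in castrated males.

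Besides Ephb6, no gene passed in the mean knockout effect. The smallest p-values that did not pass belonged to Mios, a component of the nutrient-sensing machinery upstream of mTOR (-0.55, SE 0.11, adjusted p = 0.292), Creb3l2, a membrane-bound transcription factor (-0.44, adjusted p = 0.386), and Tmed10, which carries cargo between the endoplasmic reticulum and the Golgi (0.28, adjusted p = 0.386). Ica1 (0.37) and C1galt1 (-0.39) followed. Mios, Creb3l2, Ica1 and C1galt1 lie on chromosome 6, as Ephb6 does. With array weights 6 genes passed, and these 5 joined Ephb6. Without castrated knockout array 1 the count was 2, Ephb6 and Mios. At an unadjusted p under 0.05 there were 397 genes, where 519 are expected by chance.

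In intact males the genes with the smallest p-values were Creb3l2 (-0.78, SE 0.15, adjusted p = 0.445) and Egr1, an immediate early transcription factor (-3.75, SE 0.75, adjusted p = 0.445), and neither passed. Vgf, a neuroendocrine peptide precursor, differed by -1.95, Dusp1, a phosphatase of the immediate early class, by -1.78, and Rmdn1 by at least 2.01-fold, on the higher side. The genes of catecholamine synthesis also did not pass: Th, the enzyme that makes L-DOPA, differed by -0.16, Ddc, which makes dopamine, by 0.48, Dbh, which makes noradrenaline, by 0.19, and Pnmt, which makes adrenaline, by 0.07. The Pnmt value ran from -0.50 without wild-type intact male array 2 to 0.63 without wild-type intact male array 1. Among genes of the cortex, Star, which moves cholesterol into mitochondria, differed by -0.43, Cyp11a1, which makes pregnenolone, by -0.17, Cyp11b1, which makes corticosterone, by -0.04 and Cyp11b2, which makes aldosterone, by -0.47. Akr1c18, which inactivates progesterone, was not detected on any intact male array. By limma 0 of 10375 genes passed, and 275 had an unadjusted p under 0.05. The count was 2 with array weights (Egr1 and Rmdn1) and 1 with median scaling (Egr1). It was 3 without wild-type intact male array 1 (Egr1, Dusp1 and Klf2, which was named after its value was seen) and 1 without wild-type intact male array 3 (Vgf).

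As a set, immediate early genes lay lower in knockout than in wild-type intact males, with a median over 20 genes of -1.57 (camera adjusted p = 1.48e-17, adjusted p = 0.151 with an estimated correlation). None of these genes passed over all genes and 4 were lower adjusted over the list alone. The median was -0.40 without wild-type intact male array 2. Heat shock and unfolded protein genes had a median of -0.25 (camera adjusted p = 6.66e-06, adjusted p = 0.138 with an estimated correlation). Red blood cell genes had a median of -0.37 (camera adjusted p = 0.000255, adjusted p = 0.342 with an estimated correlation). Glucocorticoid-induced genes had a median of -0.15 (camera adjusted p = 0.00254, adjusted p = 0.342 with an estimated correlation). Fibroblast genes had a median of -0.19 (camera adjusted p = 0.00602, adjusted p = 0.482 with an estimated correlation). Lists on the higher side were catecholamine genes, with a median of 0.19 (camera adjusted p = 0.00602, adjusted p = 0.482 with an estimated correlation), and chromaffin identity genes, with 0.23 (camera adjusted p = 0.00844, adjusted p = 0.572 with an estimated correlation). Exocytosis genes had a median of 0.24 (camera adjusted p = 0.00844, adjusted p = 0.342 with an estimated correlation). Lymphocyte genes had a median of 0.34 (camera adjusted p = 0.0357, adjusted p = 0.342 with an estimated correlation). In the last 8 lists 0 genes passed over all genes. Adjusted over the list alone, 1 red blood cell gene and 1 glucocorticoid-induced gene were lower, and 0 genes of the other 6 lists passed. Camera passed 9 of 29 lists, 0 of them with an estimated correlation, and fry passed 0. Camera's call, with the median in parentheses, was lost without knockout intact male array 2 for the catecholamine (0.16), chromaffin identity (0.10), exocytosis (0.16) and lymphocyte (0.22) lists and without knockout intact male array 3 for the lymphocyte (0.21) and fibroblast (-0.14) lists. A call was also lost without wild-type intact male array 1 for the exocytosis (0.14) and lymphocyte (0.22) lists and without wild-type intact male array 2 for the catecholamine (0.17), chromaffin identity (0.20), glucocorticoid-induced (-0.07), lymphocyte (0.37) and fibroblast (-0.23) lists.

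In females the largest differences among the genes with the smallest p-values after Ephb6 were in Prl8a2, a prolactin-family hormone (1.85, SE 0.55), Xlr4a (-1.71, SE 0.51) and Myo1d, a myosin (at least 1.21-fold, on the lower side), and none of these passed. Gal, the precursor of the peptide galanin, differed by 0.78 and Mios by -0.67. For the always named genes the differences were Th 0.22, Ddc 0.37, Dbh 0.38, Pnmt 0.27, Star -0.09, Cyp11a1 0.11, Cyp11b1 0.05, Cyp11b2 0.01 and Akr1c18 0.08. The Pnmt value was 0.0040 without knockout female array 1 and 0.59 without wild-type female array 1. By limma 0 genes passed, 291 had an unadjusted p under 0.05, and each alternative also gave 0. Proliferation genes lay lower in knockout females as a set, with a median of -0.39 (camera adjusted p = 5.80e-11, adjusted p = 0.116 with an estimated correlation). Chromaffin identity genes had a median of 0.41 (camera adjusted p = 2.82e-07, adjusted p = 0.391 with an estimated correlation). Catecholamine genes had a median of 0.24 (camera adjusted p = 8.02e-05, adjusted p = 0.391 with an estimated correlation). Exocytosis genes had a median of 0.17 (camera adjusted p = 0.00532, adjusted p = 0.391 with an estimated correlation). Interferon response genes had a median of -0.23 (camera adjusted p = 1.91e-06, adjusted p = 0.391 with an estimated correlation). Macrophage genes had a median of -0.08 (camera adjusted p = 0.00532, adjusted p = 0.418 with an estimated correlation). In these 6 lists 0 genes passed over all genes, and 0 adjusted over the list alone. Without knockout female array 1 the median of the catecholamine genes was 0.031, and camera's direction for the list turned to lower without passing. Camera passed 6 of 29 lists, 0 of them with an estimated correlation, and fry passed 0. Camera's call, with the median in parentheses, was lost without knockout female array 1 for the chromaffin identity (0.02) and exocytosis (0.11) lists and without knockout female array 2 for the macrophage (-0.09) list. A call was also lost without wild-type female array 1 for the macrophage (-0.10) list and without wild-type female array 2 for the exocytosis (0.14) list.

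In castrated males the genes with the smallest p-values after Ephb6 were Cldn7, a tight junction protein (1.18, SE 0.26), Malt1, a protease of lymphocyte signalling (at least 1.61-fold, on the higher side, with 2 of 3 knockout arrays detecting it), and Uaca (0.96, SE 0.20), each with adjusted p = 0.656. Fcgr2b, an inhibitory antibody receptor, differed by -0.94 and C1qb, a complement component of macrophages, by -0.56. For the always named genes the differences were Th -0.74, Ddc -0.17, Dbh -0.32, Pnmt -1.02, Star 0.02, Cyp11a1 -0.01, Cyp11b1 0.01, Cyp11b2 0.05 and Akr1c18 -0.25. By limma 0 genes passed, 651 had an unadjusted p under 0.05, and with array weights 1 passed, Ephb6. Cholesterol synthesis genes had a median of -0.50 (camera adjusted p = 1.86e-05, adjusted p = 0.551 with an estimated correlation). Macrophage genes had a median of -0.26 (camera adjusted p = 1.86e-05, adjusted p = 0.540 with an estimated correlation). Catecholamine genes had a median of -0.22 (camera adjusted p = 0.000252, adjusted p = 0.588 with an estimated correlation). Chromaffin identity genes had a median of -0.19 (camera adjusted p = 0.0102, adjusted p = 0.666 with an estimated correlation). Glutathione and xenobiotic genes had a median of -0.23 (camera adjusted p = 0.00556, adjusted p = 0.540 with an estimated correlation). Liver genes had a median of -0.77 (camera adjusted p = 0.00649, adjusted p = 0.540 with an estimated correlation). Red blood cell genes had a median of 0.27 (camera adjusted p = 0.0426, adjusted p = 0.588 with an estimated correlation). Over all genes 0 members of these 7 lists passed. Adjusted over the list alone, 2 macrophage genes and 1 catecholamine gene were lower and 0 genes of the other 5 lists passed. Median scaling moved the median of all genes by -0.26, and relative to this shift the 7 lists kept their direction in 4 of 4 scalings. Camera passed 7 of 29 lists, 0 of them with an estimated correlation, and fry passed 0. Camera's call, with the median in parentheses, was lost without knockout castrated array 2 for the liver (-0.78) and red blood cell (0.20) lists and without knockout castrated array 3 for the catecholamine (-0.17), chromaffin identity (-0.12) and red blood cell (0.29) lists. A call was also lost without wild-type castrated array 2 for the liver (-0.53) and glutathione (-0.18) lists and without wild-type castrated array 3 for the red blood cell (-0.03) list. Without castrated knockout array 1 the medians of the cholesterol (-0.29), catecholamine (-0.36), chromaffin identity (-0.36) and glutathione (-0.10) lists and the difference of Pnmt (-0.67) moved by over 1.5 times.

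For the mean knockout effect camera passed 11 of 29 lists, 0 with an estimated correlation, and fry 0, and its lowest adjusted p was 0.00129 for proliferation genes (median -0.11, and adjusted p = 0.580 with an estimated correlation). The 24 neighbours of Ephb6 on chromosome 6 had a median of -0.01 (camera adjusted p = 0.639), and 0 of them passed over all genes or adjusted over the list alone. Across genes, which are not independent replicates, the knockout effect in intact males and that in females correlated with Pearson's r = 0.137 and Spearman's rho = 0.124. The values were -0.036 and -0.015 for intact and castrated males and -0.034 and -0.056 for females and castrated males. These pairs share no arrays.

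Akr1c18, a marker of the X-zone, the inner cortical zone that regresses in male mice at puberty, was at least 282-fold higher in wild-type females than in wild-type intact males (limma adjusted p = 4.45e-13). Pik3c2g, a lipid kinase and the other X-zone marker tested, was at least 17.6-fold higher (adjusted p = 4.21e-07), and Cyp2f2, a cytochrome P450, was higher by 8.14 (SE 0.19, adjusted p = 8.35e-16). Both X-zone genes passed over all genes and adjusted over the list alone. The other large increases were Xist (at least 22.1-fold), Fetub 4.76, Vnn3 4.63, Serpinb1a 4.55, Cd1d1 4.43, Frzb 4.38, Obp2a (at least 11.4-fold) and Nrep 4.25. The largest decreases were in Susd3, at least 11.7-fold lower (adjusted p = 1.58e-06), the aldehyde dehydrogenase Aldh1a7, at least 8.34-fold lower, Acan, which encodes aggrecan (at least 6.59-fold), Cited1, a transcriptional coactivator (at least 9.02-fold), and Rarres1 (at least 5.34-fold). Drd4, a dopamine receptor (at least 5.45-fold), Kcnk1, a potassium channel (-3.13), and Hmox1, which degrades heme (-2.95), were also lower. In all, 1051 genes passed, 551 higher and 500 lower in females, 70 of them by a fitted difference over 4-fold. The count was 314 with median scaling and 2257 with array weights, and it was 689 without wild-type female array 2, 638 without wild-type female array 3 and 665 without wild-type intact male array 3.

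Proliferation genes were higher in wild-type females: 10 of 15 rose (11 higher adjusted over the list alone), among them Cdk1 1.32, Tk1 1.5 and Top2a 1.39, with a median of 0.73 (camera adjusted p = 1.16e-07, adjusted p = 0.299 with an estimated correlation). Of the cholesterol synthesis genes 6 of 18 rose (9 higher adjusted over the list alone), led by Fdps, which makes farnesyl diphosphate (1.97), and Hsd17b7 (2.25), with a median of 0.57 (camera adjusted p = 2.85e-05, adjusted p = 0.485 with an estimated correlation). In the zona glomerulosa list, the aldosterone-producing zone, 3 of 11 genes fell (6 lower adjusted over the list alone): Kcnk9 (at least 1.42-fold), Shh -1.18 and Agtr1a -0.91, with a list median of -0.91 (camera adjusted p = 0.00231, adjusted p = 0.485 with an estimated correlation). In the glutathione and xenobiotic list 6 genes rose and 3 fell of 24 (8 higher and 4 lower adjusted over the list alone), among them Fmo1 2.37, Gsta3 2.14 and Gstm2 -0.90 (camera adjusted p = 0.0471, adjusted p = 0.528 with an estimated correlation). The steroidogenesis list had 2 genes higher and 1 lower of 15 (6 higher and 4 lower adjusted over the list alone): Nr5a1, the transcription factor of steroid-producing cells (1.19), Cyp21a1 (0.57) and Cyp11a1 (-0.42, adjusted p = 0.0356), and camera did not pass it (adjusted p = 0.350). Cyp11a1 did not pass with median scaling, without a filter on dim probes, with the mean of a gene's probes or without an intensity trend. It also did not pass without wild-type female array 2 (-0.33) or 3 (-0.43) or without wild-type intact male array 1 (-0.39), 2 (-0.42) or 3 (-0.44). Star (-0.24), Cyp11b1 (0.15) and Cyp11b2 (-1.05, adjusted p = 0.0882) did not pass, though Cyp11b2 passed with array weights (-0.83). With all probes tested, a different probe of Cyp11b2, the one with its smallest p, passed (-1.27). With each of the 6 arrays compared left out in turn, Top2a passed in 4, Kcnk9 in 5, Shh in 3 and Agtr1a in 2 fits.

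Between wild-type females and intact males 1051 of all 10375 genes passed. The counts of the catecholamine, chromaffin identity and exocytosis lists are to be read against that share. Of 15 catecholamine genes 0 passed over all genes (0 adjusted over the list alone, median -0.11, camera adjusted p = 0.742), with values of Th -0.34, Ddc -0.26, Dbh -0.29 and Pnmt 0.27. The Pnmt value ran from -0.30 without wild-type intact male array 2 to 0.82 without wild-type intact male array 1. In the chromaffin identity list 1 of 19 genes fell, Cpe, which trims peptide hormones (-0.52), and 0 adjusted over the list alone (median -0.34, camera adjusted p = 0.0312, adjusted p = 0.592 with an estimated correlation). In the exocytosis list 1 gene rose and 3 fell of 23 (1 higher and 3 lower adjusted over the list alone): Cadps2, which primes dense-core vesicles (1.92), and the channel genes Kcnma1 -0.89, Kcnmb4 (at least 1.41-fold) and Cacna1h -0.68 (camera adjusted p = 0.252). Immediate early genes had a median of -1.53 with 1 of 20 lower, Jun (-1.74; 1 lower adjusted over the list alone; camera adjusted p = 0.00100, adjusted p = 0.531 with an estimated correlation), and the median was -0.34 without wild-type intact male array 2. The median of complex I genes was 0.18, with 1 of 31 higher, Ndufa6 (0.54; 1 higher adjusted over the list alone; camera adjusted p = 4.02e-05, adjusted p = 0.485 with an estimated correlation). The median of heat shock genes was -0.26, with 1 of 23 lower, Hspb1 (-1.76; 1 lower adjusted over the list alone; camera adjusted p = 0.0402, adjusted p = 0.507 with an estimated correlation). For interferon genes it was 0.23, with 1 of 20 higher, Gbp2 (0.69), and 1 higher adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.592 with an estimated correlation). Of 7 sex-chromosome genes, the X-linked Xist (at least 22.1-fold) and Kdm6a (0.81) were higher and the Y-linked Eif2s3y (at least 4.78-fold) and Kdm5d (at least 1.04-fold) lower (3 higher and 2 lower adjusted over the list alone). Of the 6 fits without 1 of the arrays compared, Cpe passed in 0, Kcnmb4 in 5, Cacna1h in 4, Gbp2 in 4, Kdm6a in 4 and Kdm5d in 1.

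Among the markers of other cells in wild-type females against intact males, endothelial genes had a median of -0.27 and 3 of 18 were lower (Ehd3 -0.62, Flt1 -0.57 and Esam -0.44), 3 lower adjusted over the list alone (camera adjusted p = 0.0180, adjusted p = 0.485 with an estimated correlation). Schwann and sustentacular genes had 1 of 7 lower, Prnp (-0.42; 1 lower adjusted over the list alone; camera adjusted p = 0.0312, adjusted p = 0.299 with an estimated correlation). Red blood cell genes had a median of -0.49 with 0 of 5 passing (0 adjusted over the list alone; camera adjusted p = 0.0317, adjusted p = 0.531 with an estimated correlation). Camera did not pass the other lists. Of these, the fibroblast list had Sparc higher (0.56) and Dcn lower (-1.12) of 18 (1 higher and 1 lower adjusted over the list alone), and the adipose list Cox7a1 higher (0.88) of 11 (2 higher and 1 lower adjusted over the list alone). The Eph list had Efna5, an ephrin, higher (0.66) of 13 (1 higher adjusted over the list alone). Of the 24 Ephb6 neighbours Gstk1 was higher (1.58) and Zyx lower (-0.40) (1 higher adjusted over the list alone). The glucocorticoid-induced list had Mt1, a metallothionein, lower (-0.63) of 19 (1 lower adjusted over the list alone). The lists with 0 genes passing over all genes were clock (12 genes, median -0.07, 0 adjusted over the list alone), macrophage (20, -0.16, 0 adjusted over the list alone), lymphocyte (7, 0.15, 0 adjusted over the list alone), smooth muscle (6, -0.06, 0 adjusted over the list alone) and kidney (6, -0.10, 1 lower adjusted over the list alone). The same held for liver (5, -0.53, 0 adjusted over the list alone), skeletal muscle (3, -0.32, 0 adjusted over the list alone) and steroid receptors (7, -0.03, 0 adjusted over the list alone), whose median turned to 0.0015 above that of all genes in 1 of 4 scalings. The pancreas genes Cpb1 (-0.45) and Cela1 (-0.10) did not pass. Camera passed 12 of 29 lists, 0 with an estimated correlation, and fry passed 9. Camera's call, with the median in parentheses, was lost without wild-type female array 2 for the chromaffin identity (-0.21), heat shock (-0.19), interferon (0.10), red blood cell (-0.36) and glutathione (-0.02) lists and without wild-type female array 3 for the heat shock (-0.19) and endothelial (-0.23) lists. A call was also lost without wild-type intact male array 1 for the chromaffin identity (-0.31), heat shock (-0.11), interferon (0.19), red blood cell (-0.37) and glutathione (0.06) lists and without wild-type intact male array 2 for the immediate early (-0.34), Schwann (-0.41) and glutathione (0.08) lists. Calls were lost as well without wild-type intact male array 3 for the chromaffin identity (-0.32), interferon (0.10), Schwann (-0.43) and red blood cell (-0.41) lists. With each of the 6 arrays compared left out in turn, Ehd3 passed in 2, Flt1 in 2, Esam in 2, Prnp in 3, Sparc in 4, Dcn in 2, Cox7a1 in 2, Zyx in 2 and Mt1 in 4 fits.

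**Figure D2:**
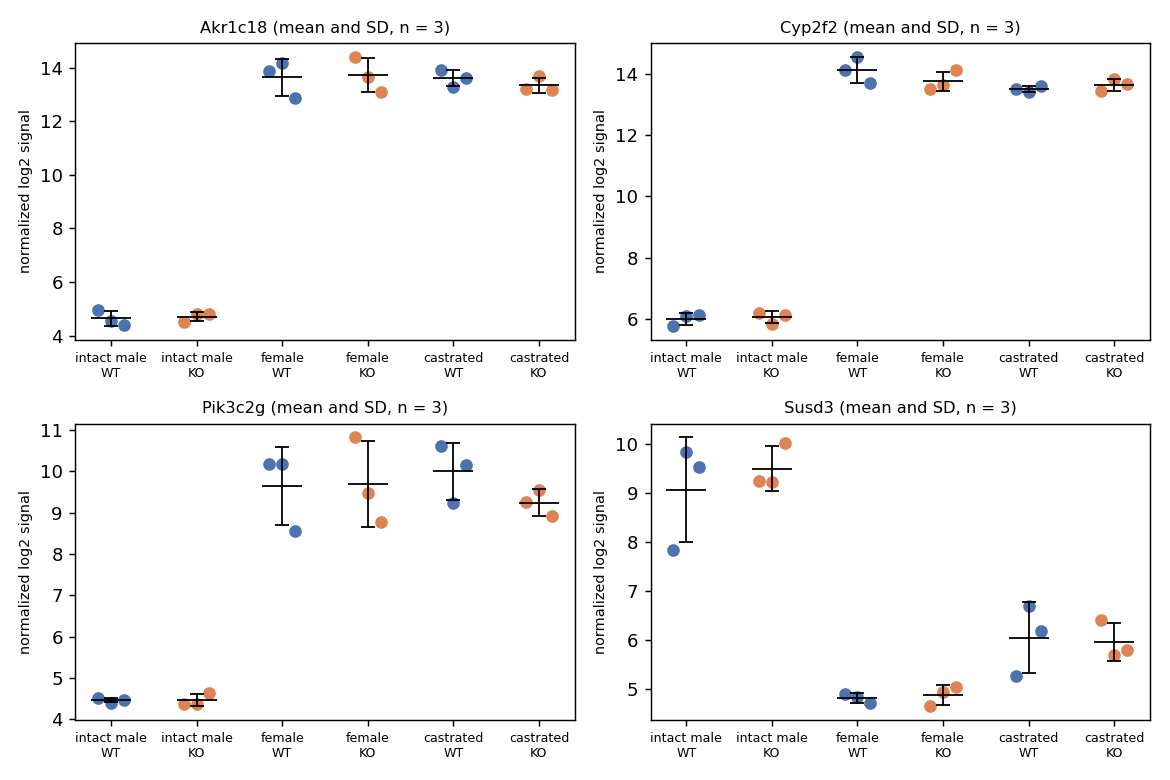
Log2 normalized intensity of Akr1c18, Cyp2f2, Pik3c2g and Susd3 on each of the 18 arrays, by condition and genotype, with points for arrays and lines for group means (n = 3). Akr1c18, Cyp2f2 and Pik3c2g are high in females and castrated males and low in intact males, by at least 282-fold and at least 273-fold for Akr1c18 in wild type, and Susd3 is high in intact males.

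In knockout mice the same contrast of females with intact males had Akr1c18 at least 314-fold higher (adjusted p = 4.32e-13), Pik3c2g at least 19.1-fold higher and Cyp2f2 higher by 7.70 (SE 0.19, limma adjusted p = 2.28e-15). Further increases were Ms4a10 4.71, Cd1d1 4.52, Xrra1 (at least 16.3-fold), Frzb 4.46, Serpinb1a 4.44, Obp2a 4.43 and Vnn3 4.30. Susd3 was at least 15.4-fold lower (adjusted p = 5.66e-07), and Acan (at least 6.49-fold), Kcnk1 -3.46, Aldh1a7 (at least 6.64-fold), Cited1 -3.31, Crym (at least 4.70-fold), Aldh1a1 -2.85 and Drd4 -2.60 were also lower. In all, 1068 genes passed, 573 higher and 495 lower, and the count was 318 with median scaling, 2048 with array weights and 661 without knockout intact male array 2. In the macrophage list 5 of 20 genes fell (5 lower adjusted over the list alone), led by the antigen-presenting class II genes H2-Ab1 -1.84, H2-Eb1 -1.73 and H2-Aa -1.49 and Cd74 -1.57, with a list median of -0.30 (camera adjusted p = 0.00215, adjusted p = 0.503 with an estimated correlation). Proliferation genes had 3 of 15 higher (3 higher adjusted over the list alone; Cdk1 0.93, Birc5 0.89 and Aurkb (at least 1.34-fold); camera adjusted p = 0.00215, adjusted p = 0.503 with an estimated correlation). Of the cholesterol synthesis genes 3 of 18 were higher (5 higher adjusted over the list alone; Fdps 1.85, Hsd17b7 1.74 and Ebp 0.79; camera adjusted p = 0.00328, adjusted p = 0.549 with an estimated correlation). In the zona glomerulosa list 4 of 11 were lower (5 lower adjusted over the list alone; Kcnk9 (at least 1.62-fold), Shh -1.33, Axin2 -1.04 and Agtr1a -0.97; camera adjusted p = 0.00504, adjusted p = 0.503 with an estimated correlation). The glutathione list had 7 genes higher and 3 lower of 24 (7 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.0250, adjusted p = 0.503 with an estimated correlation). Complex I had 3 of 31 higher (3 higher adjusted over the list alone; camera adjusted p = 0.000550, adjusted p = 0.514 with an estimated correlation). The values of Th 0.04, Ddc -0.37, Dbh -0.10 and Pnmt 0.47 did not pass. That of Pnmt ran from 0.20 without knockout female array 1 to 0.82 without knockout intact male array 1. Camera passed 6 lists, 0 with an estimated correlation, and fry passed 9. Camera's call, with the median in parentheses, was lost without knockout female array 1 for the cholesterol (0.19), zona glomerulosa (-0.18) and glutathione (0.17) lists and without knockout intact male array 2 for the glutathione (0.08) list. Of the 6 fits without 1 of the arrays compared, H2-Aa passed in 5, Cdk1 in 1, Birc5 in 1, Aurkb in 3, Shh in 4 and Agtr1a in 2.

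In wild-type castrated males, Akr1c18 was at least 273-fold higher than in intact ones (limma adjusted p = 4.88e-13), Pik3c2g at least 22.5-fold and Cyp2f2 by 7.51 (SE 0.19). Fa2h, which hydroxylates fatty acids, was at least 38.9-fold higher, and Hamp, the iron-regulating hormone hepcidin, at least 17.8-fold. The other large increases were Obp2a (at least 16.9-fold), Vnn3 4.34, Serpinb1a 4.33, Fetub 4.31, Cd1d1 4.18 and Acpp (at least 12-fold). The largest decreases were Acan (at least 6.22-fold), Rarres1 (at least 5.05-fold), Aldh1a7 (at least 7.87-fold), Susd3 -3.02 and Cited1 -3.01, with SE 0.42 and adjusted p = 0.000102 for Susd3, and Crym (at least 3.87-fold), Drd4 -2.35, Rrad -2.28 and Hmox1 -2.19 followed. In all, 1111 genes passed, 478 higher and 633 lower, 62 of them by a fitted difference over 4-fold. With median scaling 407 passed, 31% of them higher against 43.0% with quantile normalization, and the median of all genes moved by -0.16. The count was 2617 with array weights, 542 without wild-type castrated array 1, 736 without wild-type castrated array 3, 701 without wild-type intact male array 2 and 687 without wild-type intact male array 3.

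Cholesterol synthesis genes rose with castration in wild type: 11 of 18 (15 higher adjusted over the list alone), led by Fdps 2.26, Hsd17b7 2.35, Stard4 1.72 and Mvd 1.51, with a median of 0.89 (camera adjusted p = 7.22e-12, adjusted p = 0.191 with an estimated correlation). Of the steroidogenesis genes 4 of 15 rose (6 higher and 1 lower adjusted over the list alone): Nr5a1 (1.34), Mrap, a partner of the ACTH receptor (1.22), Cyp21a1 (0.54) and Cyp11b1 (0.32, adjusted p = 0.0200), with a median of 0.32 (camera adjusted p = 0.0132, adjusted p = 0.228 with an estimated correlation). Cyp11b1 did not pass with median scaling, without a filter on dim probes or without an intensity trend. It also did not pass without wild-type castrated array 1 (0.32) or 3 (0.28) or without wild-type intact male array 2 (0.32) or 3 (0.29). Star (0.33), Cyp11a1 (-0.32) and Cyp11b2 (-0.63) did not pass, though Cyp11a1 passed with array weights (-0.29). With all probes tested, a different probe of Cyp11a1, the one with its smallest p, passed (-1.06), so its probes differ in size. Of the chromaffin identity genes 5 of 19 fell (11 lower adjusted over the list alone), among them Cpe -0.86, Gata2 -0.78, Phox2a -0.81 and Cartpt -1.47, with a median of -0.60 (camera adjusted p = 9.93e-06, adjusted p = 0.529 with an estimated correlation). In the catecholamine list 4 of 15 fell (5 lower adjusted over the list alone): the noradrenaline transporter gene Slc6a2 (-2.05), Dbh (-0.94, adjusted p = 0.00940), Chgb (-0.52) and Cyb561 (-0.47), and camera did not pass the list (median -0.27, adjusted p = 0.122). Dbh did not pass with median scaling. Th (-0.63, adjusted p = 0.135), Ddc (-0.72, adjusted p = 0.0947) and Pnmt (0.75, adjusted p = 0.327, and 0.18 without wild-type intact male array 2 or 1.31 without wild-type intact male array 1) did not pass. Th passed with the replicate block (-0.63), and Ddc with array weights (-0.88) and in a fit of only the 2 groups (-0.72). With each of the 6 arrays compared left out in turn, Gata2 passed in 1, Phox2a in 2, Cartpt in 1, Slc6a2 in 0 and Cyb561 in 1 fits.

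Endothelial genes were also lower in castrated wild-type males: 10 of 18 fell (12 lower adjusted over the list alone), among them Cdh5 -1.03, Tie1 -0.91, Robo4 -0.72 and Esam -0.62, with a median of -0.52 (camera adjusted p = 2.20e-06, adjusted p = 0.0764 with an estimated correlation). In the zona glomerulosa list 4 of 11 fell (6 lower adjusted over the list alone; Shh -1.81, Kcnk9 (at least 1.34-fold), Axin2 -0.88 and Wnt4 -0.84; camera adjusted p = 0.000271, adjusted p = 0.376 with an estimated correlation). In the interferon list 6 of 20 fell (9 lower adjusted over the list alone; Ifit2 -1.19, Usp18 -0.97, Isg15 -0.96 and Rsad2 -0.87; camera adjusted p = 6.73e-05, adjusted p = 0.416 with an estimated correlation). Complex I genes had 1 of 31 higher (1 higher adjusted over the list alone; median 0.16, camera adjusted p = 0.000291, adjusted p = 0.532 with an estimated correlation). Camera did not pass the glutathione list, in which 5 genes rose and 3 fell of 24 (5 higher and 3 lower adjusted over the list alone; Ugt1a1 (at least 2.77-fold), Gsta3 2.48 and Ephx1 -1.5). It also did not pass the clock list, in which 1 rose and 2 fell of 12 (1 higher and 2 lower adjusted over the list alone; Bhlhe40 0.66, Nr1d1 -1.59 and Dbp -1.14). Of the pancreas genes, Cela1 was lower (-0.57, adjusted p = 0.00621) and Cpb1 (-0.36) did not pass. Camera passed 7 lists, 0 with an estimated correlation, and fry passed 8. Of the 6 fits without 1 of the arrays compared, Axin2 passed in 4, Wnt4 in 2, Isg15 in 3 and Dbp in 1.

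In knockout castrated males, Akr1c18 was at least 241-fold higher than in intact knockout males (limma adjusted p = 9.36e-13), Pik3c2g at least 14.0-fold, Fa2h at least 20.1-fold and Cyp2f2 by 7.59 (SE 0.19). Further increases were Obp2a 5.64, Serpinb1a 4.64, Vnn3 4.41, Hamp (at least 12.1-fold), Fetub 4.27, Acpp (at least 11.3-fold) and Lypd6 4.20, and the largest decreases were Acan (at least 5.14-fold), Aldh1a7 (at least 5.26-fold), Susd3 -3.54, Rarres1 (at least 3.19-fold), Cited1 (at least 7.14-fold), Crym (at least 3.72-fold), Aldh1a1 -2.62 and Drd4 -2.39. Th (-1.21, adjusted p = 0.00340), Ddc (-1.37, adjusted p = 0.00193) and Dbh (-1.45, adjusted p = 0.000242) fell, and Pnmt did not pass (-0.34, adjusted p = 0.649, and 0.0092 without castrated knockout array 1 or 0.011 without knockout intact male array 1). Slc6a2 was lower (-2.27) and did not pass without knockout castrated array 3 (-1.66) or without knockout intact male array 2 (-2.01). In all, 1818 genes passed, 773 higher and 1045 lower, 66 of them by a fitted difference over 4-fold. With median scaling 1356 passed, 9.07% of them higher against 42.5% with quantile normalization, and the median of all genes moved by -0.41. The count was 2783 with array weights, 1139 in a fit of only the 2 groups, 975 without knockout intact male array 2 and 1589 without the dim castrated knockout array 1.

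Chromaffin identity genes fell in castrated knockout males: 15 of 19 (17 lower adjusted over the list alone), among them Uchl1 -1.48, Gata2 -1.34, Cpe -0.93 and Dlk1 -0.73, with a median of -1.05 (camera adjusted p = 1.17e-09, adjusted p = 0.268 with an estimated correlation). Without the dim array 15 of 19 were lower. In the catecholamine list 10 of 15 fell and 1 rose (1 higher and 11 lower adjusted over the list alone), with Cyb561 -1.18 and Chgb -0.92, a median of -0.82 (camera adjusted p = 5.05e-05, adjusted p = 0.407 with an estimated correlation), and 9 lower without the dim array. The exocytosis list had 1 gene higher, Cadps2 (1.55), and 8 lower of 23, among them the synaptotagmins Syt1 -1.24, Syt4 -1.15 and Syt7 -1.04 (2 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0335, adjusted p = 0.538 with an estimated correlation), and 7 lower without the dim array. Steroidogenesis genes rose in 8 of 15 (8 higher adjusted over the list alone), with Mrap 1.60, Nr5a1 0.99, Hsd3b1 0.75 and Cyp11b1 0.37 and Star 0.77, a median of 0.37 (camera adjusted p = 0.00161, adjusted p = 0.240 with an estimated correlation), and 7 higher without the dim array. Star and Cyp11b1 did not pass with median scaling, nor Star without knockout intact male array 2 (0.67), nor Cyp11b1 in a fit of only the 2 groups. Cyp11a1 (-0.16) and Cyp11b2 (-0.12) did not pass. With all probes tested, a different probe of Cyp11a1, the one with its smallest p, passed (-1.04). Cholesterol synthesis genes had 4 of 18 higher (4 higher adjusted over the list alone; Hsd17b7 1.55, Fdps 1.44, Insig1 1.25 and Stard4 0.92; camera adjusted p = 0.00155, adjusted p = 0.538 with an estimated correlation), and 5 without the dim array. With each of the 6 arrays compared left out in turn, Syt4 passed in 5 and Stard4 in 3 fits.

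Macrophage genes also fell in castrated knockout males, 10 of 20 (12 lower adjusted over the list alone), with H2-Ab1 -1.40, C1qc -0.84, C1qb -0.75 and Fcer1g -0.67 and a median of -0.58 (camera adjusted p = 4.98e-05, adjusted p = 0.268 with an estimated correlation), and 11 without the dim array. Endothelial genes had 7 of 18 lower (10 lower adjusted over the list alone; Pecam1 -0.94 and Esam -0.43; camera adjusted p = 0.00155, adjusted p = 0.268 with an estimated correlation), and 5 without the dim array. Immediate early genes had 4 of 20 higher and 1 lower (4 higher and 1 lower adjusted over the list alone; Egr1 3.11, Nr4a2 2.79, Fosl2 0.93 and Jun -1.10; camera adjusted p = 0.00343, adjusted p = 0.538 with an estimated correlation), and 3 higher and 1 lower without the dim array. The interferon list had 4 of 20 lower (6 lower adjusted over the list alone; Ifit2 -1.14 and Ifi47 -0.89; camera adjusted p = 0.0124, adjusted p = 0.538 with an estimated correlation). The Schwann and sustentacular list had 3 of 7 lower (4 lower adjusted over the list alone; Sox10 -1.66; camera adjusted p = 0.0371, adjusted p = 0.268 with an estimated correlation). Proliferation genes had 1 of 15 higher, Birc5 (1.07; 7 higher adjusted over the list alone; camera adjusted p = 0.0306, adjusted p = 0.538 with an estimated correlation). Complex I had 3 of 31 higher (2 higher adjusted over the list alone; camera adjusted p = 0.00860, adjusted p = 0.538 with an estimated correlation). The medians of the cholesterol (0.35), proliferation (0.42) and complex I (0.16) lists turned negative as given with median scaling, and relative to the shift of all genes they kept their sign in 4 of 4 scalings. Camera passed 12 of 29 lists, 0 with an estimated correlation, and fry passed 10. Camera's call, with the median in parentheses, was lost without knockout castrated array 1 for the immediate early (0.67) and interferon (-0.30) lists and without knockout castrated array 2 for the Schwann (-0.48) list. A call was also lost without knockout castrated array 3 for the exocytosis (-0.37), Schwann (-0.41) and proliferation (0.42) lists and without knockout intact male array 2 for the exocytosis (-0.27) and proliferation (0.34) lists. Calls were lost as well without knockout intact male array 3 for the Schwann (-0.46) list. Of the 6 fits without 1 of the arrays compared, Esam passed in 2, Nr4a2 in 1, Fosl2 in 0 and Birc5 in 5.

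**Figure D3:**
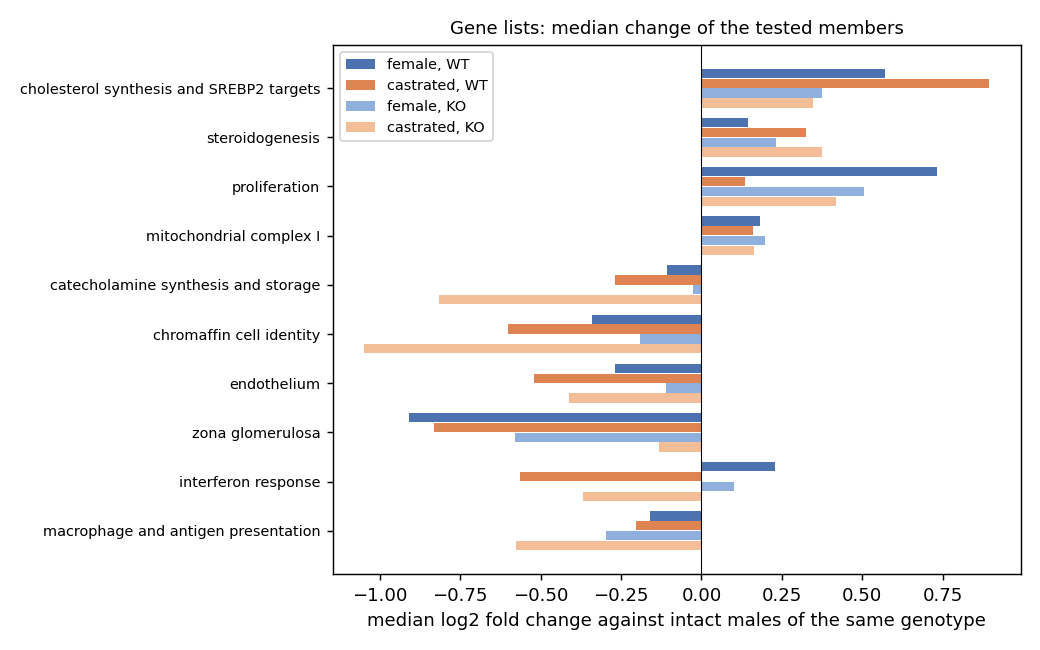
Median log2 fold change of 10 gene lists in 4 comparisons, females or castrated males against intact males in wild type or knockout, as bars from 0. The chromaffin identity list lies at -0.60 in castrated wild-type and -1.05 in castrated knockout males, and the cholesterol list is above 0 in all 4 comparisons, except that with median scaling its value in castrated knockout males falls below 0 before the shift of all genes is taken off.

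**Figure D4:**
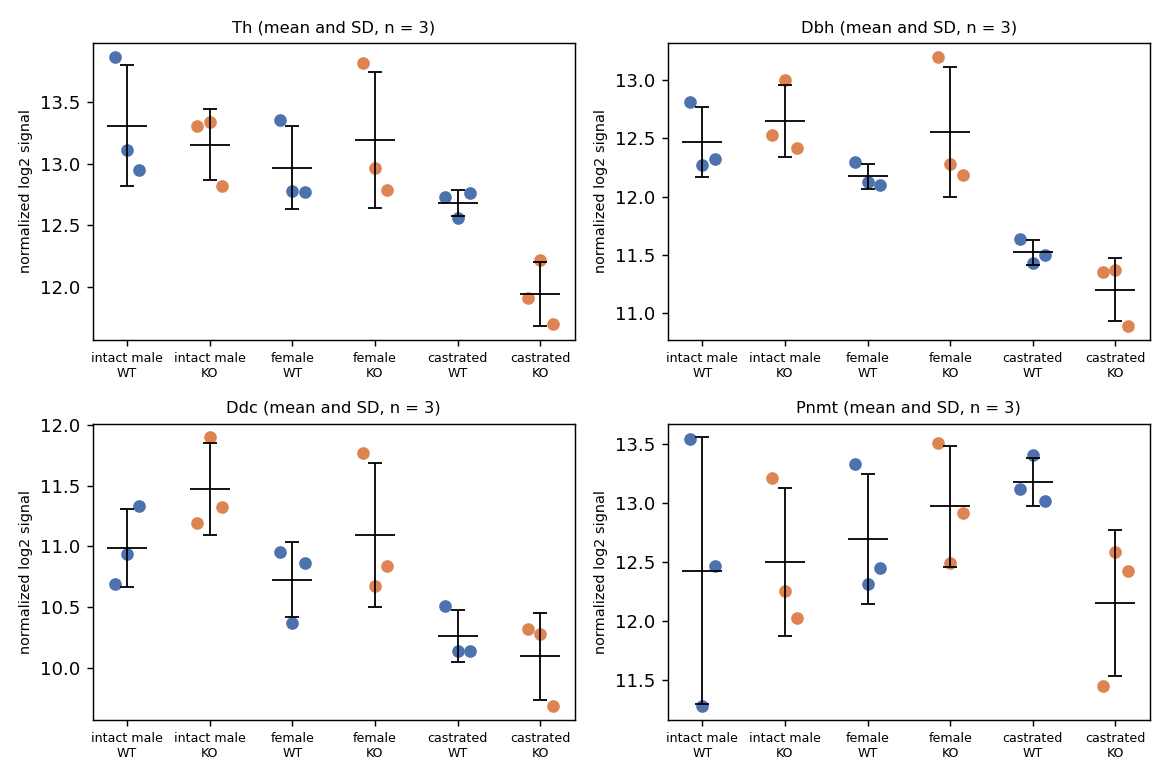
Log2 normalized intensity of Th, Dbh, Ddc and Pnmt on each of the 18 arrays, by condition and genotype, with points for arrays and lines for group means (n = 3). In castrated knockout males Th, Dbh and Ddc differ from intact knockout males by -1.21, -1.45 and -1.37, and Pnmt differs by -0.34, which is 0.0092 without castrated knockout array 1 and 0.011 without knockout intact male array 1.

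The sex and castration effects shared genes, among them Akr1c18, Pik3c2g and Cyp2f2 (higher) and Susd3, Acan and Aldh1a7 (lower), each of which passed in both effects in both genotypes. Effects taken from different genotypes share no arrays. For females in wild type and castrated males in knockout, 626 genes passed in both, 334 higher, 292 lower and 0 in opposite directions, where independent lists would share 41.1 higher and 50.4 lower. Across genes Pearson's r was 0.636 and Spearman's rho 0.538, and 95.9% of the genes that passed in the sex effect had the same sign in the castration effect. For females in knockout and castrated males in wild type, 595 genes passed in both, 305 higher, 288 lower and 2 opposite (26.4 and 30.2 for independent lists), with r = 0.739 and rho = 0.633. Within wild type, where both effects share the 3 intact male arrays, r was 0.814 and rho 0.742, against 0.5 in simulations of unchanged groups, and the covariance was 0.212 against a simulated 0.0288. There 657 genes passed in both, 326 higher and 331 lower (25.4 and 30.5 for independent lists), and 98.5% of the genes that passed in the sex effect had the same sign in the castration effect. Part of that overlap may come from the shared arrays.

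**Figure D5:**
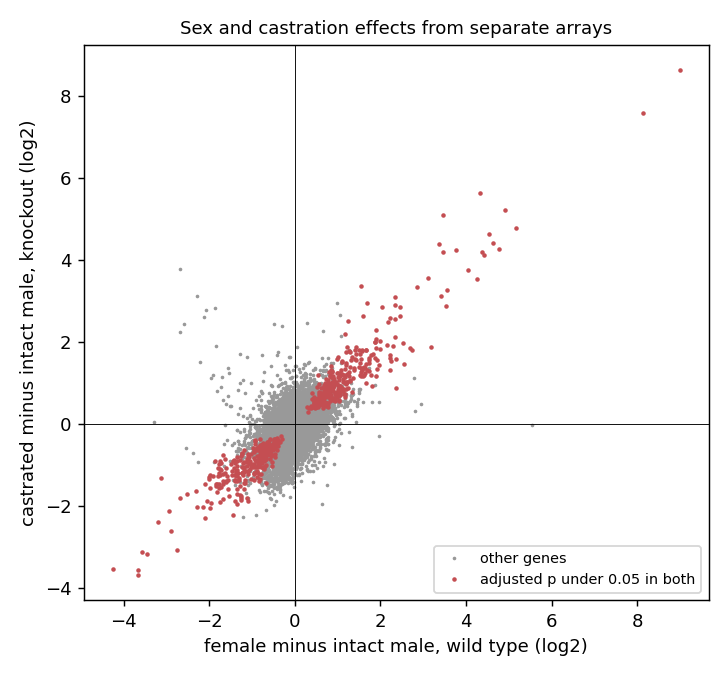
Log2 fold change of females against intact males in wild type (horizontal axis) and of castrated against intact males in knockout (vertical axis), with a point for each of 10375 genes. The genes that passed in both lie in the lower left and upper right corners, 292 lower and 334 higher, and 0 lie in the other corners.

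Both effects were also shared between genotypes. The sex effect of Akr1c18 was at least 282-fold in wild type and 314-fold in knockout, and its castration effect at least 273-fold and 241-fold, all 4 lower bounds. Of the sex effect, 719 genes passed in both genotypes, 384 higher, 334 lower and 1 opposite (30.4 and 23.9 for independent lists), with r = 0.819 and rho = 0.684. Of the castration effect, 774 passed in both, 356 higher, 418 lower and 0 opposite (35.6 and 63.8), with r = 0.768 and rho = 0.670.

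The last comparison asked whether the knockout effect differed between conditions. By limma 0 genes passed for females minus intact males, castrated minus intact males or castrated males minus females, with lowest adjusted p = 0.9998, 0.966 and 0.911. At an unadjusted p under 0.05 there were 181, 417 and 460 genes, and each alternative also gave 0. The fall of chromaffin identity genes with castration had a median of -1.05 in knockout and -0.60 in wild type. Their knockout effect differed between castrated and intact males by a median of -0.37 (camera adjusted p = 8.34e-05, and adjusted p = 0.372 with an estimated correlation), with 0 of 19 genes passing over all genes and 0 adjusted over the list alone. That median was -0.25 without castrated knockout array 3 and -0.22 without knockout intact male array 2. The difference of the catecholamine list was -0.51 (camera adjusted p = 1.66e-06, adjusted p = 0.291 with an estimated correlation), with 0 genes passing over all genes and 1 lower adjusted over the list alone. Camera passed 11, 7 and 11 of 29 lists in these 3 differences, 0 of them with an estimated correlation, and fry passed 0.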

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

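The tests of the chromosome 6 genes, of the chromaffin genes, of the array behind the immediate early genes and of other splits of the arrays were chosen only after the results were seen.

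Among the probes without a gene name, ILMN_2476405 was brighter in knockout than in wild type in all 3 conditions, the 1 such probe to pass in the knockout contrasts. It was at least 3.45-fold brighter (limma adjusted p = 2.12e-06 among 2441 probes), and the fitted mean difference of 2.69 (SE 0.22) is taken against wild-type arrays mostly at background. It averaged 7.04 ± 0.46, 7.69 ± 0.31 and 7.61 ± 0.25 (SD, n = 3) in knockout intact males, females and castrated males, and 4.50 ± 0.09, 5.22 ± 1.08 and 4.56 ± 0.11 in wild type. It was detected on 9 of 9 knockout arrays and on 1 of 9 wild-type arrays, wild-type female array 1 at 6.46, below the lowest knockout array at 6.51.

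Genes of chromosome 6, which carries Ephb6, were common among the smallest p-values of the mean knockout effect: 6 of the 20 genes other than Ephb6 with the smallest p (Mios, Creb3l2, Ica1, C1galt1, Pon3 and Clec2d), where 1.02 are expected (Fisher's exact test, one-sided, p = 0.000364). In single comparisons 4 of 20 were on chromosome 6 for the knockout in intact males (exact p = 0.0170), and 2 of 20 in females, in castrated males and in the castration effect in wild type (exact p = 0.273 each) and 1 of 20 in the sex effect in wild type (exact p = 0.650). Of 100 genotype splits within the conditions 1, the real one, gave as many, and the highest other gave 4. The splits and the exact tests count the genes that prompted them, so they describe the pattern and are not independent support against chance placement. Against an outlying array, at least 4 of the 20 genes were on chromosome 6 whichever array was left out. A candidate explanation that stays open is a chromosome segment of another strain carried along with the targeted allele: of the 94 other tested genes from the start of the chromosome to Ephb6, 7.45% had p under 0.05, against 3.74% of genes elsewhere (Fisher's exact test, one-sided, p = 0.0644), too few to decide. The 94 leave out Mios, Creb3l2, Ica1, C1galt1 and Pon3, while genes elsewhere kept their smallest p-values. The comparison therefore leans against such a segment. Along the chromosome Ephb6 is 100th of the 531 tested genes. Pon3, C1galt1, Mios, Ica1 and Creb3l2 lie on the stretch before it, at 8th, 15th, 17th, 20th and 79th. Clec2d lies outside that stretch, at 464th. The list of 24 neighbours of Ephb6, chosen before the data were examined, had a median of -0.01 and 1 gene with p under 0.05, and an effect of the missing receptor on the 6 genes was not tested.

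Chromaffin genes were lower in castrated than in intact males, with 5 of 19 identity genes called in wild type and 15 in knockout. Against the dim array as the source, 15 of 19 were lower in knockout without castrated knockout array 1. A lower share of medullary cells would lower Pnmt like the 33 other markers, and Pnmt lay above their mean change by 1.30 (SE 0.54) in wild type and by 0.61 (SE 0.54) in knockout. With each array left out in turn the gap ran from 0.79 to 1.81 in wild type, past 2 SE in 4 of 6 fits, and from 0.35 to 1.06 in knockout, past 2 SE in 0 of 6, so a lower share cannot be told apart from changed expression, which stays open as untested. The difference of the chromaffin list between castrated males and females in knockout effect was -0.63 (camera adjusted p = 1.24e-07, adjusted p = 0.310 with an estimated correlation), and -0.30 without knockout female array 1.

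Immediate early genes were lower in knockout than in wild-type intact males as a set, with a median of -1.57, and the difference of the knockout effect between females and intact males was 1.66 (camera adjusted p = 1.20e-11, adjusted p = 0.213 with an estimated correlation). Without wild-type intact male array 2 the median was -0.402 and that difference 0.50, so a single wild-type array with high immediate early genes may account for most of the median, while Egr1 was then -2.955 against -3.75 with all arrays. Without wild-type intact male array 1 the median was -2.48, the difference 2.53 and Egr1 passed (-4.62, adjusted p = 0.0316), without wild-type intact male array 3 the median was -1.76, and without any of the knockout arrays it lay between -1.62 and -1.5. In the other conditions the knockout effect on the list was 0.06 in females and 0.22 in castrated males, where it was -0.19 without castrated knockout array 1. The contrast between the conditions, which flagged the list, was lost with an estimated correlation. It cannot tell a biological difference of the knockout effect apart from a single wild-type array, so a biological difference was not tested.

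Further differences of knockout effects between conditions, each given as the median of the list, passed camera and were lost with an estimated correlation. For castrated minus intact males the immediate early genes differed by 1.84 (camera adjusted p = 7.90e-10, adjusted p = 0.291 with an estimated correlation), and by 0.56 without wild-type intact male array 2. The cholesterol synthesis genes differed by -0.72 (camera adjusted p = 1.66e-06, adjusted p = 0.291 with an estimated correlation), and by -0.38 without knockout intact male array 1. The catecholamine genes differed by -0.51 (camera adjusted p = 1.66e-06, adjusted p = 0.291 with an estimated correlation). The red blood cell genes differed by 0.55 (camera adjusted p = 3.92e-05, adjusted p = 0.291 with an estimated correlation), and by 0.29 without wild-type castrated array 3. For castrated males minus females the catecholamine genes differed by -0.54 (camera adjusted p = 1.24e-07, adjusted p = 0.310 with an estimated correlation), the liver genes by -1.09 (camera adjusted p = 0.00341, adjusted p = 0.310 with an estimated correlation) and the proliferation genes by 0.63 (camera adjusted p = 5.10e-06, adjusted p = 0.310 with an estimated correlation). Without knockout female array 1 these were -0.20, -0.64 and 0.42, and the liver value was -1.69 without wild-type castrated array 3. In all, camera passed 11 lists for females minus intact males, 7 for castrated minus intact males and 11 for castrated males minus females.

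Other splits of the arrays into groups of the same sizes were counted for each number of genes called. For the 3 knockout comparisons there are 10 splits each, too few for a share under 0.05, and 10 of 10 called as many genes, which a real count of 0 makes certain, so these say nothing: the real counts were 0, 0 and 0 and the highest others 1 in intact males, 1 in females and 3 in castrated males. For the sex and castration comparisons there are also 10 splits, too few for a share under 0.05, and 1 of 10, the real one, called as many: the real counts were 1051, 1111, 1068 and 1818 and the highest others 0, 1, 0 and 0. For the mean knockout effect 7 of 100 splits called as many as the real 1, the highest other being 1, so chance is not excluded for that count. The splits counted any gene, so they do not test whether Ephb6, the targeted gene, is lower. For the 3 differences of knockout effects the 100 of 100 splits that called as many say nothing either, as the real count was 0, and the highest others were 2, 1 and 2.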

How the results depend on the processing

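Leaving out the dim castrated knockout array 1 and counting the calls of list members without each array were chosen only after the data were seen, and the other alternatives were planned. Over the alternatives, 224 of 249 counts of called genes stayed within 1.5 times the main count and 25 moved. Of 5790 values of named genes 5744 stayed on their side of the threshold, 23 lost it, 23 gained it and 0 turned. Of 5655 values of lists 5093 stayed, 387 lost it, 172 gained it and 3 turned, and 35 of 35 correlations stayed. Of 1920 values of the genes with the largest changes 1918 stayed past the threshold. Mean Ephb6 passed under every alternative, with adjusted p between 0.000622 and 0.0244.

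With array weights the counts were 2 for the knockout in intact males, 1 in castrated males, 6 for its mean, 2257 and 2048 for sex in wild type and knockout, and 2617 and 2783 for castration. With median scaling they were 1 for the knockout in intact males, 314 and 318 for sex and 407 for castration in wild type. Without the dim array the mean knockout effect had 2 genes, and with only the arrays of the groups compared castration in knockout had 1139. The cause was not tested. With the estimated correlation 0 lists passed in all 11 contrasts, against 6 to 12 with the preset one, and fry passed 0 in the 4 knockout contrasts and the 3 differences of knockout effects.

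Leaving out each array in turn gave 0 to 3 genes for the knockout in intact males, 1 to 2 for its mean, 638 to 1082 and 661 to 963 for sex in wild type and knockout, 542 to 1048 and 975 to 1774 for castration, and 0 elsewhere, and the cause was not tested. Without knockout female array 1, 3 lists turned direction by camera. The median of the catecholamine genes in knockout females was then 0.031 (0.031 to 0.39 over all arrays left out). For females minus intact males that of the catecholamine genes was -0.16 (-0.16 to 0.18) and that of the zona glomerulosa genes 0.21 (-0.22 to 0.21). The cause was not tested. Of the list members named by the rule that passed, 23 of 44 and 28 of 52 for sex in wild type and knockout and 37 of 55 and 50 of 82 for castration passed whichever array was left out, and all kept their sign.

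The replicate numbers showed no pairing across the arrays as a whole: 5 of 21 pairs of arrays with the same number correlated above 0.1 (-0.193 to 0.233), and 4 of 18 arrays lay closest to their own number. The highest value, 0.233, was that of wild-type and knockout intact male arrays 1, so a link within single pairs is not excluded. With the replicate block the counts were 1014 and 1026 for sex, 1068 and 1755 for castration, 1 for the mean knockout effect and 0 elsewhere. A slide block was not run, as no slide is named in the sources used here. Signal over background limits dim genes: the lowest detected value was 5.36 to 6.50 in log2 intensity, near Ephb6, whose mean effect was -0.37 without background correction and -0.42 in the authors' normalized values.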

Other observations

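The comparison of Ephb6 between wild-type groups and the fits of the genes named here without each array were chosen only after the values were seen.

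Several genes moved the same way with sex and with castration in both genotypes. Within a genotype both effects are taken against the same 3 intact male arrays, so their values are not independent. Cadps2, which primes dense-core vesicles, was higher by 1.92 and 1.67 in wild-type and knockout females and by 1.89 and 1.55 in castrated males. Gstk1, a mitochondrial and peroxisomal glutathione transferase gene near Ephb6 on chromosome 6, was higher by 1.58, 1.5, 1.29 and 1.32 in the same order. Hspb1, a small heat shock protein, was lower, with values of -1.76, -1.72, -1.83 and -1.24, and so was Jun, an immediate early transcription factor, with -1.74, -1.29, -1.39 and -1.10. All 16 values passed limma with n = 3 arrays per group, and did so whichever 1 of the 6 arrays compared was left out. Efna5, an ephrin, was higher by 0.66, 0.55, 0.48 and 0.38 in the same order, and each value passed with all arrays. For castration it passed in 4 of the 6 fits without 1 array in wild type and in 2 of 6 in knockout.

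Castration also changed members of the clock list and of the steroid receptor list, which camera did not pass. Nr1d1, a repressor of the clock, was lower (-1.59 in wild type and -1.39 in knockout), and Bhlhe40 was higher by 0.66 and 0.85. Hsd17b1, which makes estradiol from estrone, was higher by 1.11 and 1.23. Gper1, a membrane estrogen receptor, was lower in castrated than in intact knockout males (-1.64). In wild type its difference between castrated and intact males was -0.71 and did not pass (limma adjusted p = 0.162). All of these values but that of Gper1 in wild type passed, and did so whichever 1 of the 6 arrays compared was left out. Among the other genes refitted, Dbp in wild type (-1.14) and Per2 (1.09), Cry2 (1.025) and Cyp17a1 (1.90) in knockout passed with all arrays. With each array compared left out in turn, Dbp, Per2, Cry2 and Cyp17a1 each passed in only 1 of the 6 fits. The genes given first are thus the steadier ones among those refitted. The time of day of tissue collection is not given in the sources used here.

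Ephb6 RNA in wild type was higher in females than in intact males by 0.78 (SE 0.26, limma adjusted p = 0.0690) and in castrated than in intact males by 0.77 (adjusted p = 0.0698), and neither difference passed. Probes without a gene name passed in the sex and castration comparisons as well, 134 and 138 for sex in wild type and knockout and 118 and 231 for castration.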
